A study of Caenorhabditis elegans with 14 samples.

How the data were processed

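Young adult worms kept at 16 °C and moved to 25 °C after birth were fixed in 1% formaldehyde for 10 min, per the labels' protocols, and EAP-1 antibody ChIP and input libraries were size-selected at 300 to 600 bp and sequenced as 50-bp single-end reads. The authors deposited aligned reads as 14 files of positions, and the count of reads per bin used here was computed from them. The authors aligned the reads with Bowtie, per the submitters' processing notes, and its version, the genome build and any filter on repeated reads are not given in the sources used here. The files hold 1 line per read with chromosome, start, end and strand, and every read is 50 bp long. The labels' text mentions fewer inputs than the 6 used here.

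Files were assigned to 12 libraries (6 ChIP and 6 input) by their titles, and the 2 runs of replicate 2 of WT and of spr-5 G20 ChIP were pooled. The labels call the WT and spr-5 G20 replicates separate biological repeats. In the 12 files other than EAP1-null, lines were in position order, and all but spr-5 G20 ChIP 1 held 0.0316 to 0.491 times as many positions seen exactly 2 times as an even spread of reads would give, with 12.2 times in spr-5 G20 ChIP 1. The EAP1-null ChIP and input were not in position order and held 5.90 and 2.83 times as many, so the EAP1-null files may have been handled differently upstream, and 1 read was kept per 5' position and strand in every library. Each 5' end was moved 150 bp downstream, and reads were counted in 5-kb bins of the 6 nuclear chromosomes.

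The build was checked against the tRNA genes of WBcel235, whose bodies lose reads that map to more than 1 place. Over 612 tRNA genes, the gaps in coverage lay 0 to 93 bp from their positions in WBcel235, depending on the part of the chromosome, so the files use another build. Gene regions, promoter windows and gene lists, fixed before the data were examined, were therefore not run, and the analysis in 5-kb bins, fixed then as the main one for that case, was used by coordinates only.

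Counts were tested with edgeR 4.0.16 (quasi-likelihood, R 4.3.3) in 1 fit over the 12 libraries with a mean per group, on bins with at least 60 reads over the libraries (19951 of 20056 bins). Scaling was TMM from 10-kb bins, residual degrees of freedom were 4, the common dispersion was 0.00701, and the Benjamini-Hochberg threshold was 0.05. Groups with 1 library were assumed to vary like the replicated groups. The comparisons were WT ChIP against WT input, and the difference of ChIP and input between EAP1-null, spr-5 G10 or spr-5 G20 and WT and between spr-5 G20 and spr-5 G10. SE was the log2 change divided by the square root of its F statistic. By the rule fixed beforehand, the bins named were up to 5 rises and 5 falls past the threshold, or the 5 with the smallest p where fewer than 5 passed. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were run as alternatives. DESeq2 used the TMM scaling and means from its generalized linear model, a setting chosen after its default recovered no changed bin in simulated counts. It called 0 bins in the real data before and after that change.

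Each tool was tested on simulated counts drawn from the real bins' means and library sizes over 19951 bins, with 200 bins changed by 1.25-, 1.5- or 2-fold. All libraries were given the same spread around shared bin means, so the unevenness particular to spr-5 G20 ChIP 1 was not simulated. The recovery rates may therefore be too high for the real counts. edgeR called 15 unchanged bins for WT ChIP against WT input, 1 for EAP1-null, 5 for spr-5 G20 and 4 for spr-5 G10 against WT, and 0 for spr-5 G20 against spr-5 G10. DESeq2 recovered 95.5%, 22.7%, 30.3%, 42.4% and 3.0% of the 2-fold changes in these comparisons in the order given, and limma-voom recovered 90.9% in the first and 0 in the others.

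Arms were the outer 30% at each end of the 5 autosomes and centres the middle 40%. Each ChIP library was set against the input of its own number, as fixed before the data were examined, with log2 ratios of summed positions, and the right end of chromosome I, which holds ribosomal RNA genes, was left out. The sum of all inputs, as the alternative reference, makes differences between ChIP libraries independent of the input of each. For correlations over this shared reference, 200 sets of unchanged libraries and inputs were simulated with the inputs' own spread per 100-kb bin, drawn independently between bins. Intervals came from 2000 bootstrap draws of 1-Mb blocks and describe precision within 1 library pair. WT and spr-5 G20 were compared with a two-sided exact permutation test. Reads at the right end of chromosome I and mitochondrial reads were counted with every read kept, since the dense reads there fill the available positions. Stretches gained or lost in a genotype were searched in 5000-bp bins (at least 1.6 times the expected positions, 100 or more expected) and 200-bp windows (at most 0.25 times, and 0.15 times over the stretch, 30 or more expected), with thresholds chosen after the data were seen. Broad stretches poor in reads were searched in 500-kb windows (under 0.9 times the expected positions in spr-5 G20 input 1, at least 2 in a row), also after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

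Alternatives fixed before the data were examined were all reads kept, DESeq2 size factors, library totals, no filter on low counts, no shift of reads, DESeq2, limma-voom, ChIP libraries alone, either run alone, replicate blocks, each replicate left out, autosomes only, arms of 25%, the sum of all inputs, and 5-kb bins for library quality. Added after the data were seen were leaving out both spr-5 G20 libraries numbered 1 (with each tool), 100-kb bins and crossed replicate numbers.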

Results

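EAP-1 binding was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole young adult Caenorhabditis elegans. EAP-1 is a chromodomain protein studied for its binding to chromatin methylated at H3K9, a mark that lies mainly on the arms of the worm's autosomes. SPR-5 is a homolog of the histone H3K4 demethylase LSD1, and spr-5 mutants lose fertility over successive generations. The series covered wild type (WT, generation 0), spr-5(by101) mutants at generations 10 and 20 (G10 and G20), and a mutant labelled EAP1-null as the control for signal that does not need EAP-1. WT and spr-5 G20 had 2 numbered ChIP replicates and 2 numbered inputs each, and spr-5 G10 and EAP1-null had 1 ChIP library and 1 input each, which gave 12 libraries. Single libraries had no replicate check of their own.

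Depth differed widely. The WT ChIP libraries held 3731987 and 19975197 aligned reads, spr-5 G10 ChIP held 8297987, and EAP1-null ChIP held 4952306. The spr-5 G20 ChIP libraries held 64122 and 7978102 reads. The inputs held 5759818 and 19414352 reads in WT, 15804937 in spr-5 G10, 2138425 and 5991682 in spr-5 G20, and 3376197 in EAP1-null. The 2 sequencing runs of replicate 2 shared 9.08 times (WT) and 32.5 times (spr-5 G20) as many positions as chance gave, and were counted as 1 library. The median 5-kb bin held 2 positions in spr-5 G20 ChIP 1 and 783 in WT ChIP 2, so values from spr-5 G20 ChIP 1 alone carry large counting error. The densest 1% of 1-kb bins held 12% of the positions of spr-5 G20 ChIP 1 (95% Wilson interval 11.8 to 12.3%) and between 1.73% and 3.16% of those of the other 11 libraries. Intervals on counts cover counting error only.

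The reads were first searched for stretches gained or lost in the labelled genotypes. Summed over the spr-5 libraries (ChIP and input, G10 and G20), reads were missing on chromosome I from 14289801 to 14299400, with 37 positions against 2849 expected from the other libraries, a ratio of 0.0130 (95% exact Poisson interval 0.00914 to 0.0179). The WT and EAP1-null libraries lay between 0.975 and 1.02 there. By itself spr-5 G20 ChIP 1 was too shallow to decide, with 1 position against 4.88 expected. The EAP1-null libraries held 2 positions against 50.0 expected on chromosome II from 7857001 to 7857400, a ratio of 0.0400 (0.00485 to 0.145). The EAP1-null ChIP and input also held 1.97 times the expected positions on chromosome V from 17220001 to 17480000 (1.95 to 1.99) and 4.37 times from 18700001 to 18725000 (4.27 to 4.48). These coordinates are those of the deposited files, and no gene was assigned to them because the genome build is not given in the sources used here and differs from that of the gene table used here. The stretches come from sets defined by the labels. They show what libraries of a label share, not which mutations the worms carried.

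**Figure D1:**
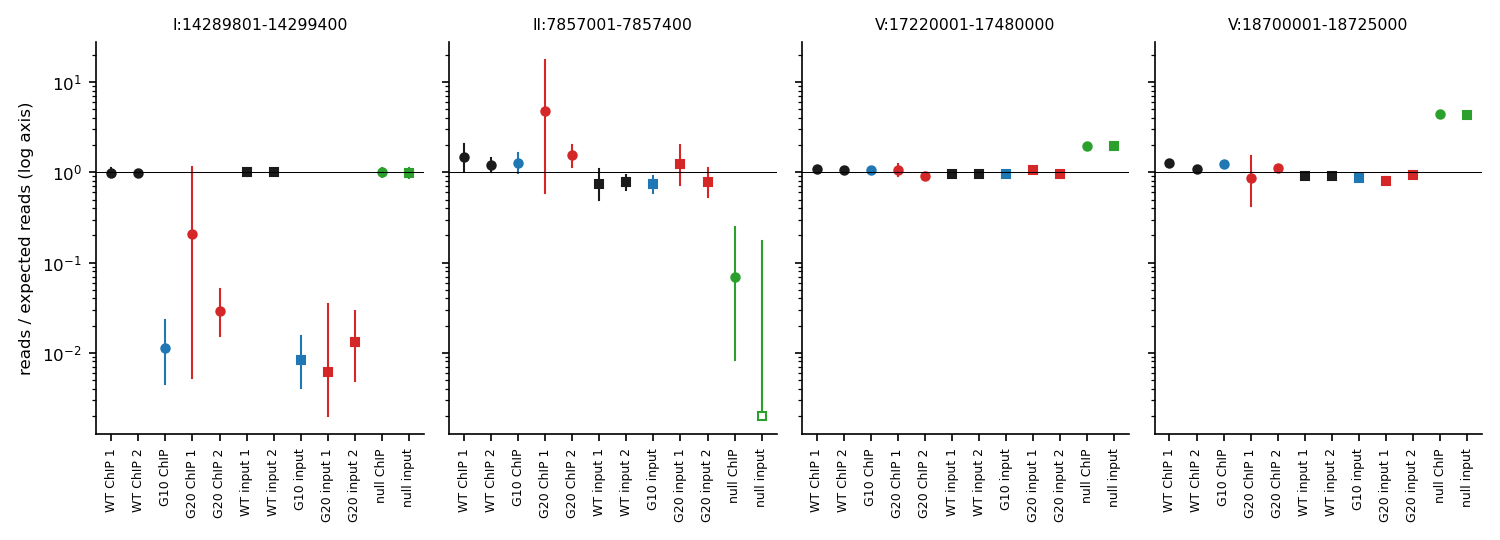
Positions over expected positions (log axis) in each library at 4 stretches, with 95% exact Poisson intervals; circles are ChIP, squares are input, black is WT, blue spr-5 G10, red spr-5 G20 and green EAP1-null, and the open square marks a count of 0 drawn at the foot of the axis. The spr-5 libraries are low on chromosome I, and the EAP1-null libraries are low on chromosome II and near 1.97 and 4.37 on chromosome V.

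Where EAP-1 antibody signal lay in WT was asked by setting WT ChIP against WT input. At the scale of chromosomes, WT ChIP 1 was higher on autosome arms than on autosome centres by 0.25 log2 units (95% block bootstrap interval 0.21 to 0.29) and was above its centre on 10 of 10 arms. The largest values were 0.37 on the left arm of III, 0.35 on the right arm of I and 0.35 on the right arm of V. WT ChIP 2 differed far less, by 0.029 (0.011 to 0.047), with 7 of 10 arms above their centre. With own inputs the WT mean was 0.14 ± 0.16 (SD, n = 2), an arm excess smaller than the spread between the replicates. The spread depended on the reference taken. With the sum of all inputs as the reference for every ChIP library, the arm values were 0.16 (0.12 to 0.19) and 0.11 (0.093 to 0.13), a mean of 0.13 ± 0.030 (SD, n = 2). This reference does not remove a bias that a ChIP library shares with its own input. With no reference, log2 arms over centres was 0.551 and 0.509 in the WT ChIP libraries and 0.303 and 0.480 in their inputs. Over 100-kb bins with no reference, Pearson's r with the own input was 0.506 in WT ChIP 1 and 0.933 in WT ChIP 2. X minus autosomes was -0.17 (-0.21 to -0.12) in WT ChIP 1 and -0.033 (-0.048 to -0.018) in WT ChIP 2, or -0.16 and -0.052 with the sum of all inputs.

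In 5-kb bins, edgeR's quasi-likelihood test called 0 of 19951 bins at an adjusted p of 0.05, with 843 bins at an unadjusted p under 0.05 and a smallest adjusted p of 0.914. DESeq2 also called 0 (879 unadjusted), as did limma-voom (1237 unadjusted). The 5 bins with the smallest p, none of which passed, all lay on right arms. On chromosome I they were 14070001 to 14075000 (log2 0.55 ± 0.13 SE), 13785001 to 13790000 (0.58 ± 0.14), 13585001 to 13590000 (0.54 ± 0.13) and 13810001 to 13815000 (0.57 ± 0.14), and on chromosome V 17930001 to 17935000 (0.50 ± 0.12). Each was above its own input in both WT replicates, from 0.66 to 1.03 in replicate 1 and from 0.30 to 0.46 in replicate 2. The bins were ranked on these same libraries, so this is no separate support. In simulated counts this test recovered 74.6% of bins changed 1.5-fold and 97% of those changed 2-fold. Those counts left out the unevenness of spr-5 G20 ChIP 1, so 0 calls in the real data do not exclude changes of this size. With both spr-5 G20 libraries numbered 1 left out, an alternative chosen after seeing the data, edgeR called 74 bins, and DESeq2 and limma-voom still called 0. Of these, 64 were higher in ChIP, with 51 on right arms and 28 of those on I.

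**Figure D2:**
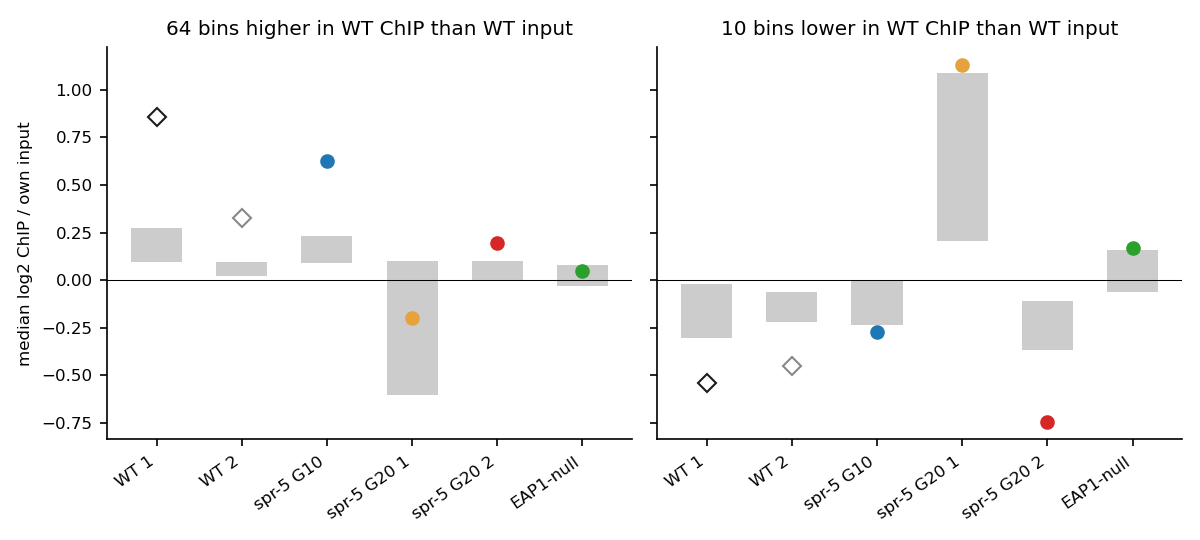
Median log2 ChIP over own input, per library, of the 64 higher (left) and 10 lower (right) bins that edgeR alone called when both spr-5 G20 libraries numbered 1 were left out, an alternative chosen after seeing the data. Open diamonds are the WT libraries used to choose the bins, and grey marks the middle 95% of 10000 random sets matched on mean reads and region.

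**Figure D3:**
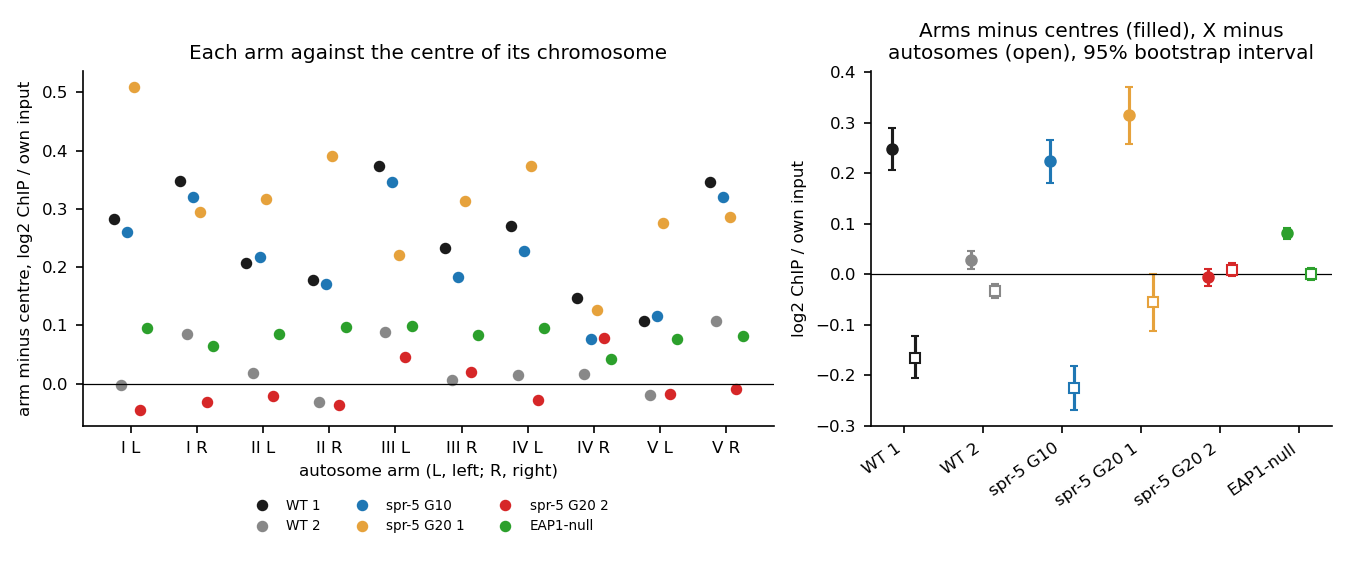
Left, log2 ChIP over own input of each autosome arm minus the centre of its chromosome, 1 point per library. Right, arms minus centres (filled circles) and X minus autosomes (open squares) per library with 95% block bootstrap intervals. WT ChIP 1, spr-5 G10 and spr-5 G20 ChIP 1 lie above 0 on all 10 arms, as does EAP1-null at 0.042 to 0.098.

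Signal that remained without EAP-1 was measured in EAP1-null. Its arms lay above its centres by 0.081 (0.070 to 0.092), with all 10 arms above their centre in a narrow range from 0.042 to 0.098, and its X chromosome lay at 0.0008 relative to the autosomes (-0.012 to 0.013). With own inputs the EAP1-null arm value was below that of WT ChIP 1 and above that of WT ChIP 2, and it differed from the WT mean by -0.057, less than the WT SD of 0.16. Without WT ChIP 1 this difference was 0.052. With the sum of all inputs the EAP1-null arm value was 0.026 (0.0067 to 0.048), below both WT libraries, and differed from the WT mean by -0.11, against a WT SD of 0.030. That SD comes from 2 ChIP libraries and does not hold the spread between inputs. With no reference, log2 arms over centres ran from 0.303 to 0.480 in the inputs. It was 0.340 in the EAP1-null input and 0.422 in the EAP1-null ChIP. The X value differed from the WT mean by 0.10 with own inputs (WT SD 0.094) and by 0.13 with the sum of all inputs (WT SD 0.073). With 1 EAP1-null library these differences were not tested.

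In 5-kb bins, edgeR called 0 bins between EAP1-null and WT after input correction, with 143 at an unadjusted p under 0.05. DESeq2 called 0 (170 unadjusted) and limma-voom 0 (349 unadjusted). The 5 bins with the smallest p did not pass, at an edgeR adjusted p of 1. They were X 11095001 to 11100000 (log2 -0.71 ± 0.21 SE), V 6995001 to 7000000 (-0.68 ± 0.22), X 6005001 to 6010000 (0.68 ± 0.23), V 9645001 to 9650000 (0.77 ± 0.27) and IV 2660001 to 2665000 (-0.83 ± 0.28). In simulated counts edgeR recovered 50.0% of 2-fold and 4.5% of 1.5-fold changes in this comparison. Without the inputs it called 31 bins, all higher in EAP1-null and all between 17225001 and 18725000 on V, the part of the genome where the EAP1-null input was high as well.

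The change at generation 10 was asked by setting spr-5 G10 against WT. The spr-5 G10 library had arms above centres by 0.22 (0.18 to 0.27), again on 10 of 10 arms, with the left arm of III (0.35), the right arm of V (0.32) and the right arm of I (0.32) highest. Its X chromosome lay at -0.23 (-0.27 to -0.18) relative to the autosomes. Along the genome its log2 ratio and that of WT ChIP 1, each over its own input, had a Pearson's r of 0.952 and a Spearman's rho of 0.918 across 996 bins of 100 kb, which are not independent replicates. The r of spr-5 G10 was 0.589 with WT ChIP 2 and 0.587 with EAP1-null. With the sum of all inputs it was 0.939 with WT ChIP 1, 0.876 with WT ChIP 2 and -0.103 with EAP1-null, against 0.195, 0.211 and 0.191 for simulated unchanged libraries that share such a reference. The covariances were 0.0212, 0.0116 and -0.00109, and 0.00150, 0.00160 and 0.00148 in the simulations. With the inputs split 3 against 3, so that no input entered both sides, r ranged over 20 splits from 0.766 to 0.943, from 0.600 to 0.906 and from -0.505 to 0.308. The simulated values do not cover what real libraries without antibody share along chromosomes, because bins were drawn independently. Over the sum of all inputs, the r of spr-5 G10 ChIP was 0.655 with WT input 2 and 0.670 with spr-5 G20 input 2. With the other inputs it ran from -0.652 to -0.154. The spr-5 G10 arm value was 0.085 above the WT mean, less than the WT SD of 0.16, and -0.025 from WT ChIP 1. With the sum of all inputs it was 0.15 (0.11 to 0.18), only 0.013 above the WT mean, against a WT SD of 0.030. Its X value was below both WT libraries. With own inputs it lay -0.13 from the WT mean (WT SD 0.094) and -0.059 from WT ChIP 1. With the sum of all inputs it lay -0.096 from the WT mean (WT SD 0.073) and -0.044 from WT ChIP 1. With 1 library this was not tested.

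In 5-kb bins, edgeR called 0 bins between spr-5 G10 and WT, with 72 at an unadjusted p under 0.05, DESeq2 called 0 (55 unadjusted) and limma-voom 0 (0 unadjusted). The 5 bins with the smallest p all lay on the left arm of III and did not pass, at an edgeR adjusted p of 1. They started at 1950001 (log2 0.62 ± 0.21 SE), 1205001 (0.68 ± 0.25), 2115001 (0.49 ± 0.18), 1870001 (0.57 ± 0.22) and 2475001 (0.49 ± 0.19). In simulated counts edgeR recovered 74.2% of 2-fold and 13.4% of 1.5-fold changes. Without the inputs, edgeR called 2 bins, 14290001 to 14295000 and 14295001 to 14300000 on chromosome I, where spr-5 libraries lacked reads.

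**Figure D4:**
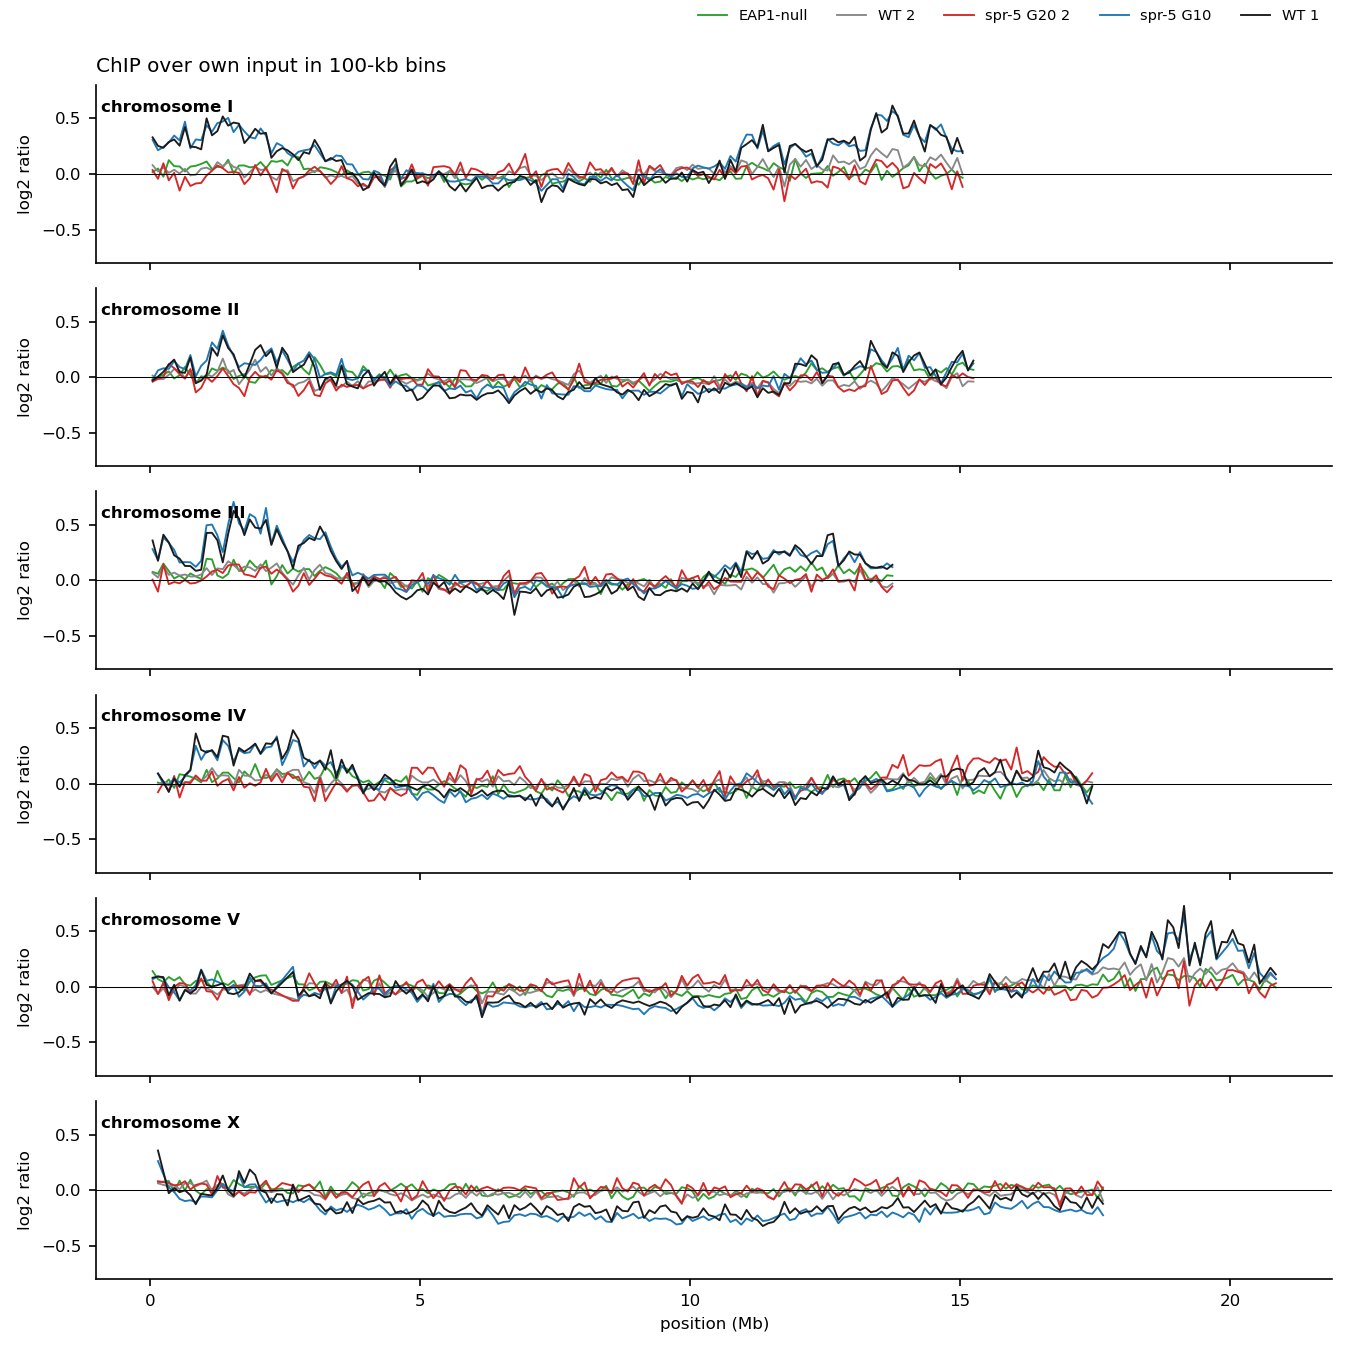
Log2 ChIP over own input in 100-kb bins along the 6 chromosomes (position in Mb) for WT ChIP 1 and 2, spr-5 G10, spr-5 G20 ChIP 2 and EAP1-null; spr-5 G20 ChIP 1 is left out for its depth. WT ChIP 1 and spr-5 G10 run together (r = 0.952), with their largest arm values on the left arm of III and the right arms of I and V.

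Whether binding had changed by generation 20 was asked by setting spr-5 G20 against WT, the only pair of groups with replicates on both sides. The spr-5 G20 replicates did not resemble each other. Arms exceeded centres by 0.32 (0.26 to 0.37) in spr-5 G20 ChIP 1 and by -0.0061 (-0.023 to 0.011) in ChIP 2, with 10 and 3 of 10 arms above their centre. The mean was 0.15 ± 0.23 (SD, n = 2) against 0.14 ± 0.16 in WT, a difference of 0.017 (two-sided exact permutation test, p = 1.0, where 2 against 2 cannot go below 0.333). X minus autosomes was -0.055 (-0.11 to -0.0001) and 0.0090 (-0.0041 to 0.022), a group difference of 0.077 (exact permutation p = 0.667). The X difference depended on the libraries taken, since WT was at -0.17 and -0.033, and it was 0.042 between the libraries sequenced in 2 runs. Among libraries sequenced in 1 run the arm values were 0.25 in WT and 0.32 in spr-5 G20, and among those sequenced in 2 runs 0.029 and -0.0061. With the sum of all inputs these were 0.16 and 0.30, and 0.11 and 0.051, and the group difference was 0.042 (exact permutation p = 1.0). With own inputs, leaving out spr-5 G20 ChIP 1 turned the arm difference to -0.14, and leaving out WT ChIP 2 turned it to -0.093.

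In 5-kb bins, edgeR called 0 bins between spr-5 G20 and WT, with 224 at an unadjusted p under 0.05. DESeq2 called 0 (280 unadjusted) and limma-voom 0 (668 unadjusted). The bin with the smallest p was X 5000001 to 5005000, at log2 1.12 ± 0.24 SE (edgeR adjusted p = 1). It rested on spr-5 G20 ChIP 2, at 1.40 over its input, while spr-5 G20 ChIP 1 was at -0.51. The other 4, which did not pass, were I 920001 to 925000 (-0.85 ± 0.25), V 19010001 to 19015000 (-0.69 ± 0.20), I 14895001 to 14900000 (-0.68 ± 0.20) and IV 5140001 to 5145000 (1.00 ± 0.31). Counts of calls depended on single libraries, with 30 bins called without spr-5 G20 ChIP 2, 58 without spr-5 G20 input 2, and 1 (the X bin) with both libraries numbered 1 left out, an alternative chosen after seeing the data. In simulated counts edgeR recovered 63.6% of 2-fold and 16% of 1.5-fold changes.

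**Figure D5:**
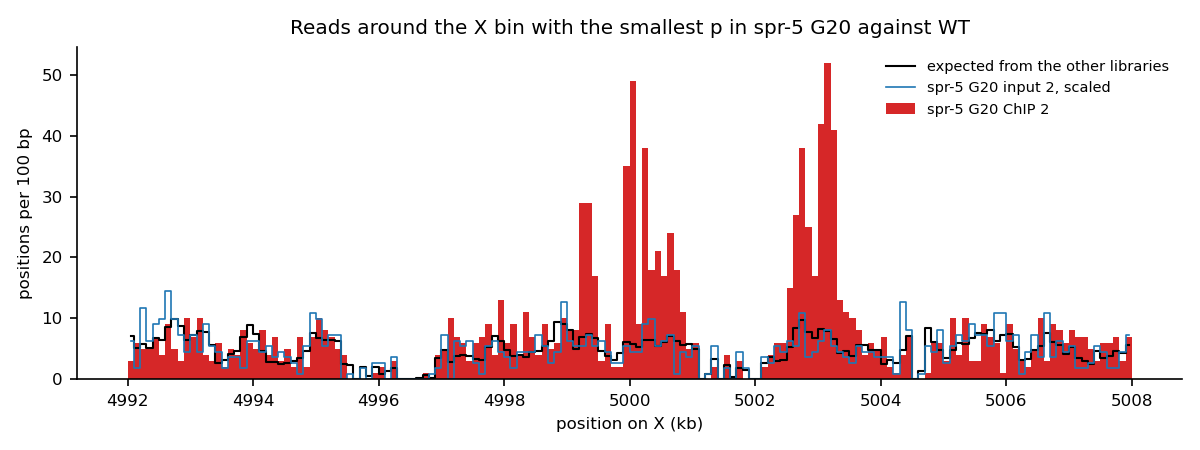
Positions per 100 bp around the X bin with the smallest p, for spr-5 G20 ChIP 2 (red bars), the number expected from the other libraries (black line) and spr-5 G20 input 2 scaled to the same depth (blue line). The stretch from 4995001 to 5005000 held 919 positions in spr-5 G20 ChIP 2 against 423 expected.

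The change between generations was tested directly by setting spr-5 G20 against spr-5 G10. The same X bin, 5000001 to 5005000, had the smallest p, at log2 1.45 ± 0.28 SE (edgeR adjusted p = 0.523). The other 4 bins with the smallest p did not pass either (edgeR adjusted p = 0.950) and were lower in spr-5 G20. They were I 14890001 to 14895000 (-0.89 ± 0.24), I 920001 to 925000 (-1.01 ± 0.28), V 19010001 to 19015000 (-0.81 ± 0.23) and I 13435001 to 13440000 (-0.86 ± 0.24). In these, spr-5 G20 ChIP 1 held only 1 to 6 positions. Its ratios over its input were 0.64, 0.34, -1.94 and 0.69 in that order. Those of spr-5 G20 ChIP 2 were -0.76, -0.58, -0.32 and -0.22. At the scale of arms, the spr-5 G20 mean lay -0.069 from the spr-5 G10 value (spr-5 G20 SD 0.23) with own inputs, and 0.029 from it (SD 0.18) with the sum of all inputs. X minus autosomes was higher than in the 1 spr-5 G10 library in both spr-5 G20 libraries, with means 0.20 apart (spr-5 G20 SD 0.045) with own inputs and 0.15 apart (SD 0.041) with the sum of all inputs, a difference that was not tested. In all, edgeR called 0 bins (760 unadjusted), DESeq2 0 (741 unadjusted) and limma-voom 0 (14 unadjusted). The X bin alone was called without the inputs, without spr-5 G20 ChIP 1, and with both libraries numbered 1 left out, while 3 bins were called without spr-5 G20 ChIP 2 and 68 without spr-5 G20 input 2. In simulated counts edgeR recovered 51.5% of 2-fold and 6.0% of 1.5-fold changes.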

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

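The comparison of mitochondrial reads in this part was chosen after the values were seen, and the X values were fixed as a measure beforehand. X minus autosomes, as log2 ChIP over own input, was -0.17 and -0.033 in the WT replicates and 0.0008 in EAP1-null, so every WT library lay on the other side of 0 from the null. The value in spr-5 G10 was -0.23, again opposite in sign to the null's 0.0008. In spr-5 G20 it was -0.055 in ChIP 1 and 0.0090 (-0.0041 to 0.022) in ChIP 2, the latter on the null's side of 0. Differences from the null were not tested, and the null's interval (-0.012 to 0.013) includes 0. With the sum of all inputs the values were -0.16 and -0.052 in WT, -0.20 in spr-5 G10 and -0.076 and -0.019 in spr-5 G20. The null was then at 0.026 (0.012 to 0.038).

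Mitochondrial reads lie outside the comparisons of nuclear bins. Their share in ChIP over their share in the own input was 1.18 and 1.15 in WT, 0.995 in spr-5 G10 and 1.77 in spr-5 G20 ChIP 2, each above the 0.464 (95% exact interval 0.453 to 0.476) of EAP1-null. The spr-5 G20 ChIP 1 value was 0.209, from 21 reads. The inputs differ in these shares, at 0.470% in EAP1-null and between 0.157% and 0.324% in the others, while the ChIP shares were 0.218% in EAP1-null, 0.384% and 0.287% in WT, 0.318% in spr-5 G10 and 0.377% in spr-5 G20 ChIP 2, so part of each fold comes from the input. Every read was kept in these shares, and the EAP1-null files may have been handled differently upstream. No biological or technical explanation of these shares was tested.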

How the results depend on the processing

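The left-out pair, 100-kb bins and crossed numbers were chosen after the results were seen. Of 122 counts of called bins under alternatives, 110 were 0, as in the fit reported. Without inputs the counts were 31 for EAP1-null, 3 for spr-5 G20 and 2 for spr-5 G10 against WT, and 1 for spr-5 G20 against G10; the 2 bins lost in spr-5 lie where those libraries lack reads and the 31 where the null input is high. With both spr-5 G20 libraries numbered 1 left out, edgeR called 74 bins in WT, 1 for spr-5 G20 against WT and 1 against G10, while DESeq2 and limma-voom called 0. Leaving out each replicate gave 0 to 58 bins for spr-5 G20 against WT and 0 to 68 against spr-5 G10. The cause was not tested.

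Arms minus centres ranged over left-out replicates from -0.14 to 0.18 for spr-5 G20 minus WT (-0.093 without WT ChIP 2, -0.14 without spr-5 G20 ChIP 1), from -0.025 to 0.19 for spr-5 G10 minus WT, and from -0.17 to 0.052 for EAP1-null minus WT. Within spr-5 G20 itself they ranged from -0.0061 (without ChIP 1) to 0.32, and X minus autosomes from -0.055 to 0.0090 (without ChIP 1). The other 42 values of groups and of differences from WT, under 25% arms, all reads or the sum of inputs, kept their sign, but the sum of inputs moved arms minus centres from 0.081 to 0.026 in EAP1-null, from 0.22 to 0.15 in spr-5 G10, from 0.085 to 0.013 for spr-5 G10 minus WT, from 0.017 to 0.042 for spr-5 G20 minus WT and from -0.057 to -0.11 for EAP1-null minus WT. It moved X minus autosomes from -0.023 to -0.048 in spr-5 G20 and from 0.0008 to 0.026 in EAP1-null, and 25% arms moved spr-5 G20 minus WT from 0.017 to 0.0007 for arms. The sum of inputs turned spr-5 G20 minus spr-5 G10 from -0.069 to 0.029 for arms, and spr-5 G20 ChIP 2 from -0.0061 to 0.051 for arms and from 0.0090 to -0.019 for X. Over all alternatives, the 5 named bins together ran from -1.97 to 1.26 for spr-5 G20 against WT and from -2.10 to 1.66 against spr-5 G10. Without spr-5 G20 ChIP 2, 6 values of named bins turned. Over left-out replicates, spr-5 G20 against WT ran from -0.51 to 1.23 (X 5000001), from -1.07 to 0.40 (I 920001) and from -0.63 to 1.26 (IV 5140001), and against spr-5 G10 from -0.18 to 1.56 (X 5000001), from -0.93 to 0.55 (I 14890001) and from -1.23 to 0.24 (I 920001). The cause was not tested.

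In 5-kb bins the top 1% held 1.77%, 1.50%, 1.65%, 7.56% and 1.51% of positions in WT ChIP 1 and 2, spr-5 G10 ChIP and spr-5 G20 ChIP 1 and 2, 1.77%, 1.73%, 1.65%, 2.45% and 1.82% in their inputs, and 1.94% and 1.98% in EAP1-null ChIP and input, because larger bins even out counts.

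Deviations of same-numbered samples correlated at -0.033 (WT ChIP and input), 0.366 (spr-5 G20 ChIP and input), -0.111 (ChIP of WT and spr-5 G20) and 0.024 (their inputs). The main fit had no replicate block, as planned, and these correlations did not set that choice. The values over own inputs still follow the numbers, as planned, although the WT correlation gives that pairing no backing. A replicate block by number, or by genotype and number, called 0 bins for WT ChIP against input and 0 for spr-5 G20 against WT. With numbers crossed within or between genotypes the block also called 0 in each. Gene regions, promoter windows and gene lists were not run. Depth limits spr-5 G20 ChIP 1 most, at a median of 2 positions per 5-kb bin.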

Other observations

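Apart from the thinning test of spr-5 G20 ChIP 1, the tests in this part were chosen after the results were seen. The 74 bins that edgeR alone called in WT when both spr-5 G20 libraries numbered 1 were left out lay mainly on chromosome ends. Of 64 bins higher in ChIP, 51 were on right arms and 10 on left arms, 3 on X and 0 in centres, while 24.8%, 24.5%, 17.7% and 33.0% of tested bins lay there; 31 were on I and 23 on the right arm of V. The 10 lower bins included 5 on X. In libraries not used to choose them, the median log2 ratio of the 64 bins was 0.63 in spr-5 G10 (above 0 in 64 of 64 bins) and 0.20 in spr-5 G20 ChIP 2 (55 of 64), in each case above 100% of 10000 random sets matched on mean reads and region. It was 0.049 in EAP1-null (42 of 64), above 83.0% of such sets, and -0.20 in spr-5 G20 ChIP 1 (25 of 64), above 64% of them. The sets were not matched on chromosome or on neighbouring bins, so the percentages do not treat 64 independent bins. In spr-5 G10 the right arms lay above their centres by 0.076 on IV and by 0.32 on I and V. The 10 lower bins had medians of -0.27 in spr-5 G10 and -0.74 in spr-5 G20 ChIP 2, above 0.34% and 0% of their matched sets. Their medians were 0.17 in EAP1-null and 1.13 in spr-5 G20 ChIP 1, above 98.3% and 98.6%.

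The right end of chromosome I (15060001 to 15070000), where ribosomal RNA genes lie, held a higher share of reads in ChIP than in the own input in WT (1.46-fold and 1.08-fold), spr-5 G10 (1.32-fold) and spr-5 G20 (4.63-fold and 1.45-fold), and 1.00-fold (95% exact interval 0.987 to 1.02) in EAP1-null. These folds count every read. Repeats made up 9.66% of nuclear reads in the EAP1-null ChIP and 3.42% in its input, files that may have been handled differently upstream. How far this moved the EAP1-null fold was not tested. With 1 read per position they were 10.3 in spr-5 G20 ChIP 1, 0.759 in EAP1-null and between 1.11 and 1.91 in the other ChIP libraries. Part of each fold comes from the input, whose share of reads there ran from 0.468% in spr-5 G10 to 1.08% in WT input 2. The EAP1-null ChIP share was 0.998%, above 0.619% in spr-5 G10 and 0.855% in spr-5 G20 ChIP 2. It was below 1.32% and 1.16% in WT and 3.04% in spr-5 G20 ChIP 1. Chromosome IV held broad stretches poor in reads in both spr-5 G20 libraries numbered 1. From 13500001 to 17000000 the input held 0.724 (0.689 to 0.758) and the ChIP 0.681 (0.622 to 0.741) of the positions expected from the libraries of the other genotypes and generations, and from 5000001 to 6500000 they held 0.875 and 0.815. The other 10 libraries lay between 0.962 and 1.09 in the first stretch and between 0.953 and 1.05 in the second. The remaining 2 stretches found, on III and V, were also low in other inputs. Base composition, which varies along chromosomes and affects read yield, was not analysed here.

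With own inputs, arms were above centres in WT ChIP 1 and spr-5 G10 and differed little from them in WT ChIP 2 and spr-5 G20 ChIP 2. The gap between the WT replicates was 0.22 against their own inputs and 0.042 (0.022 to 0.060) against the sum of all inputs. A shared reference cancels between ChIP libraries, so the fall is the 0.18 by which the WT inputs differ and is no separate test. Unlike inputs remain a candidate, but the fall cannot tell them from a bias that a ChIP library shares with its own input. With no reference, r with the own input over 100-kb bins was 0.933 in WT ChIP 2 and 0.506 in WT ChIP 1. With every read kept the gap was 0.228, inside the interval of 0.188 to 0.248, but this cannot decide whether repeat reads matter. Repeats were few in the files, at 1.49% of reads in WT ChIP 1 and 1.88% and 1.77% in the runs of WT ChIP 2. The 23.6% in WT ChIP 2 as a whole comes mostly from pooling these runs, which share positions. Any repeats removed before deposit were out of reach. Genotype or generation stays open for the spr-5 libraries: against the sum of inputs spr-5 G10 lay 0.096 (0.063 to 0.13) above spr-5 G20 ChIP 2, more than the 0.042 between the WT replicates and less than the 0.25 between the spr-5 G20 replicates.

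Reads on X from 4995001 to 5005000 were in excess in spr-5 G20 ChIP 2, at 2.17 times the expected number (2.04 to 2.32) and in both of its runs (731 and 666 reads). A copy gain in the worms is argued against by spr-5 G20 input 2, at 0.978 (0.891 to 1.07). A peak of bound fragments should displace the strands by 120 bp, but they matched best at -10 bp (r = 0.639 against 0.405). DNA from another source that holds separate blocks of the region could give such a profile and stays open, since the minus strand was at 4.06 (3.53 to 4.65) in blocks picked on the plus strand and at 1.57 (1.19 to 2.02) beside them, an interval that spans the bound of 1.5. No biological explanation beyond binding and copy gain was tested.

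The densest 1% of 1-kb bins held 12% of positions in spr-5 G20 ChIP 1. Low depth alone is argued against, because spr-5 G20 ChIP 2 thinned to as many positions reached 5.88% at most in 20 draws. The right end of chromosome I alone is argued against as well, since the share without it was 9.54% (9.31 to 9.78%). What concentrates these reads stays open, and no biological explanation was tested.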
